A study of Mus musculus with 4 samples.

How the data were processed

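Gene expression was measured in Paneth cells, the granule-filled secretory cells at the base of small intestinal crypts, cut by laser capture from frozen sections of male NMRI mice of 8 weeks. One group of mice was germ-free. The other had been germ-free and was then conventionalized for 10 days, that is, given the gut microbes of a conventionally raised mouse. Per the labels' protocols, RNA of 3 mice per group was pooled in equal amounts, and 2 aliquots of 10 ng from each pool were amplified with a linear amplification kit for small samples (Arcturus RiboAmp HS). The product was labelled with biotin, and each aliquot went onto 1 Affymetrix mouse expression array. The 2 arrays of a group are therefore repeat amplifications of 1 pool. Every p-value below sets the difference between the 2 pools against amplification and array error alone. The spread between mice cannot be had from these arrays, and their number limits the precision.

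The deposited table held 1 signal intensity per probe set and array on a linear scale, as the authors computed it. In the deposited values the mean after trimming 2% from each end was 250 on all 4 arrays, so the table counted as already scaled by the authors and was left as it was. The software and version behind these intensities are not given in the sources used here. The table held 45101 probe sets, of which 64 were array controls. Present and absent calls were not used here. The scanner parameter files were read for batches only. All 4 arrays shared 1 chip lot, 1 scanner, 1 hybridization day and 1 scan day. Both germ-free arrays were washed on fluidics station 1 and both conventionalized arrays on station 2, so station and group cannot be told apart.

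Intensities were turned into log2(intensity + 32), the pseudocount being the power of 2 next above the 20th percentile of all values, which understates the change of dim probe sets. Folds are given on this scale. Probe sets entered the test where their mean over the 4 arrays was above the median of all probe sets, a signal of 113.9, and control probe sets were left out. This left 22491 probe sets. The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend of the variance on mean signal), and a probe set was called at a Benjamini-Hochberg adjusted p under 0.05 in either direction. The prior degrees of freedom came out as infinite, beside 2 residual degrees of freedom per probe set, so every standard error quoted is that of probe sets of like signal and not that of the probe set itself. The fit was checked on simulated data with the real probe sets' means and a spread smoothed over probe sets of like signal. It recovered 1 of 50 probe sets changed by a log2 of 1 and 33 of 50 changed by 2. Of those changed by 3 it recovered 44 of 50, and of those changed by 4 all 50, with 14 false calls. A simulation with no changed probe set gave 3 calls. Both simulations gave probe sets of like signal a common spread, as the fit itself assumes, so they cannot show how far that assumption holds. The 4 arrays can be split into 2 and 2 in 3 ways only, so a permutation test could not go below p = 0.333.

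Gene symbols came from the platform annotation of 2016, matched by gene identifier to a mouse gene table of assembly GRCm38.p6. Of the probe sets, 34958 named 1 gene, 932 named several and 9211 named none there. Of those naming 1 gene, 34754 found their identifier in the table, and no symbol needed an update. The deposited values name no genome build, so no coordinates are given. Each gene stands for its probe set with the highest mean signal. In all, 12113 genes had that probe set tested. Probe sets with several genes name none here. Suffixes _s_at and _x_at mark probes that can bind related transcripts, which matters for the alpha-defensins, for Lyz1 with Lyz2, and for the Reg3 genes.

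The following were fixed before the data were examined: the test, the filter, the pseudocount rule, 32 gene lists and the rule for the genes named. That rule took Reg3g, Reg3b, Lyz1, Ang4, Mmp7, Pla2g2a, Fut2, Angptl4 and the alpha-defensins whatever their values, the 12 called genes with the largest rise and the 12 with the largest fall where the groups do not overlap, and up to 4 members of each list (called members with the largest change, otherwise the brightest). Genes outside this rule are said to have been chosen after their values were seen. For each list, called members were counted over all probe sets tested and adjusted over the list alone. The median log2 difference was placed among the medians of 10000 random lists of the same size, matched on mean signal in 20 bins of rank. That percentile describes these arrays and is no p-value. The top bin joins the very brightest genes with less bright ones, so lists of very bright genes are matched only loosely.

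Alternatives planned beforehand were pseudocounts of 8 and 128, no filter, a filter keeping the brightest 25% of probe sets, quantile normalization, median centring, the aliquot number as a block, eBayes without the trend, the median over all probe sets of a gene, and leaving out each array in turn. Array weights, a robust variance prior, a fixed prior of 4 degrees of freedom, the crossed aliquot block and leaving out arrays for the count of pairwise differences were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.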

Results

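The data set held 4 arrays of laser-captured Paneth cells, 2 from a pool of 3 germ-free mice and 2 from a pool of 3 mice conventionalized for 10 days. Duplicate amplifications of a pool had a standard deviation of the log2 difference of 0.83 in the germ-free and 1.05 in the conventionalized group. Between duplicates, 21.1% and 29.9% of the 22491 probe sets tested lay more than 2-fold apart. Across probe sets, which are not independent replicates, the Pearson correlation of duplicates was 0.869 for germ-free and 0.779 for conventionalized. Conventionalized replicate 2 correlated at 0.754 to 0.779 with the 3 other arrays, whereas germ-free replicate 2 and conventionalized replicate 1, from different pools, correlated at 0.890. Duplicate error had a standard deviation of 0.93 (germ-free) and 1.36 (conventionalized) among the 7497 dimmest probe sets. Among the 7497 brightest it was lower, at 0.59 and 0.66. The fitted standard error, shared by probe sets of like signal, rose again at the highest signals. It was 0.42 for Cklf, with signals from 559 to 3864, but 1.16 for Lyz1, with signals from 24112 to 249594. For Reg3b, Defa31 and Rps18, also very bright, it was 0.90, 1.01 and 1.14.

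The comparison of conventionalized with germ-free cells asked how colonization of the gut altered gene expression in Paneth cells. At the brightest probe set of each gene, the largest rise was that of Reg3g (gene identifier 19695), which encodes a secreted lectin that kills Gram-positive bacteria. Its signal was 786 and 1460 on the germ-free arrays and 26467 and 41251 on the conventionalized arrays, a log2 difference of 4.90 ± 0.50 (SE, 2 arrays per group; limma adjusted p = 2.9e-18) or 29.9-fold. Retnlb, a secreted resistin-like protein with antibacterial activity, rose 11.5-fold (log2 difference 3.53 ± 0.51). Dmbt1, a mucosal scavenger receptor protein that binds bacteria, rose 8.78-fold, and Mptx1, a pentraxin of the gut epithelium, rose 6.69-fold. Dmbt1 was not called with either conventionalized array left out or with median centring, nor was Mptx1 with median centring. In the other direction Cubn, an endocytic receptor for vitamin B12 bound to intrinsic factor, fell by 3.23 on the log2 scale, and Mbl2, a mannose-binding lectin of the complement system, fell by 3.19 and lost its call with either germ-free array left out.

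In all, limma called 75 probe sets, 27 higher and 48 lower in the conventionalized pool. Of the 22491 tested, 1154 had an unadjusted p under 0.05, about the share that this threshold gives where nothing differs. All 75 differed by at least 2-fold, and in 73 both arrays of one group lay beyond both of the other. Counted by the brightest probe set, 13 genes were higher and 30 lower. With median centring in place of the authors' scaling, the split was 6 higher and 21 lower. These calls rest on the variance trend: without it, or with a fixed prior of 4 degrees of freedom, limma called 0 probe sets. In these fits 975 and 464 had an unadjusted p under 0.05, fewer than that threshold gives where nothing differs. Reg3g, first in rank without the trend, had a limma adjusted p of 0.128 there. Leaving out 1 array moved the counts to 22 higher and 24 lower without germ-free replicate 1, 34 and 7 without germ-free replicate 2, 32 and 181 without conventionalized replicate 1, and 14 and 33 without conventionalized replicate 2.

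**Figure D1:**
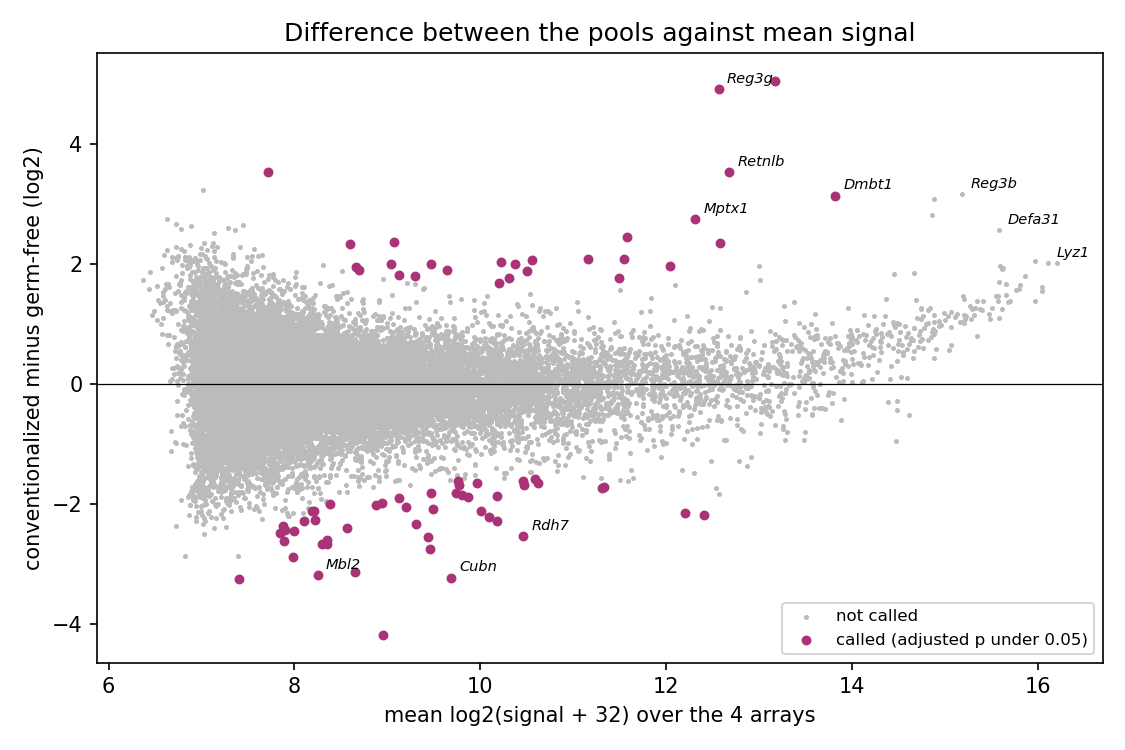
Each point is 1 of the 22491 probe sets tested, with its mean log2(signal + 32) over the 4 arrays on the x axis and the conventionalized minus germ-free log2 difference on the y axis; the 75 called probe sets are coloured and some genes are named at their brightest probe set. Among the 200 brightest probe sets 96.5% lie above 0, with a median of 0.86, and the genes named there that were not called (Lyz1, Defa31, Reg3b) lie at 2.00, 2.56 and 3.15.

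Paneth granule proteins were higher as a group. Of 15 measured members, 14 had a log2 difference above 0, with a median of 1.25, above all 10000 random lists. Reg3g and Mptx1 rose over all probe sets tested, and 7 members passed when adjusted over the list alone. The interferon, antigen presentation and ribosomal protein lists also stood at percentile 100, and the respiratory chain at 99.99. The percentile therefore does not set the Paneth list apart. Mmp7, the metalloproteinase that activates alpha-defensins, had signals of 3824 and 4418 in germ-free and 17041 and 15232 in conventionalized cells, a log2 difference of 1.96 ± 0.54 that did not pass over all probe sets (limma adjusted p = 0.068). The brightest probe set of Reg3b, a relative of Reg3g, differed by 3.15 ± 0.90 (limma adjusted p = 0.088), while its other probe set differed by 5.05 and was called. Ang4, an antimicrobial ribonuclease, differed by 1.25 ± 0.66 at its brightest probe set and by 1.96 at a second one that was called. Lyz1, the Paneth cell lysozyme, differed by 2.00 ± 1.16 and was not called. Pla2g2a, a bactericidal phospholipase of Paneth cells, differed by 0.51 ± 0.55. With quantile normalization, the list median was 0.82, 13 of 15 members stayed above 0 and 4 were called, but Lyz1 came to -0.12.

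Alpha-defensins, the main antimicrobial peptides of Paneth granules, were among the brightest signals. Defa31 differed by 2.56 ± 1.01 and Defa39 by 1.82 ± 0.75, and neither was called over all probe sets, although both passed when adjusted over the list alone and both were called without germ-free replicate 2. The list median of 2.19 was 2.96 there, 1.43 without germ-free replicate 1 and 1.53 without conventionalized replicate 2, with 0 called in the last pair. Duplicates of Defa31 differed widely, at 10553 and 38475 in germ-free and 57727 and 245509 in conventionalized cells. Defa3 lay under the signal filter, with 28 and 88 against 22 and 171. A probe set naming both Defa30 and Defa24, chosen after its values were seen, differed by 1.55 and was not called. The list median rests on 2 measured members of 40 fixed. The probes can bind several family members, so these values stand for mixtures. Ribosomal proteins, also bright, were above 0 in 40 of 43 members, with a median of 0.77, and respiratory chain genes in 73 of 88, with a median of 0.31, and no member of either was called. With quantile normalization these medians were 0.22 and 0.09, and that of the alpha-defensins was 1.31. Without germ-free replicate 1 the respiratory chain median was -0.02, with 41 of 88 above 0, and the ribosomal one 0.39; without germ-free replicate 2 they were 0.64 and 1.25, with 1 ribosomal member called.

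**Figure D2:**
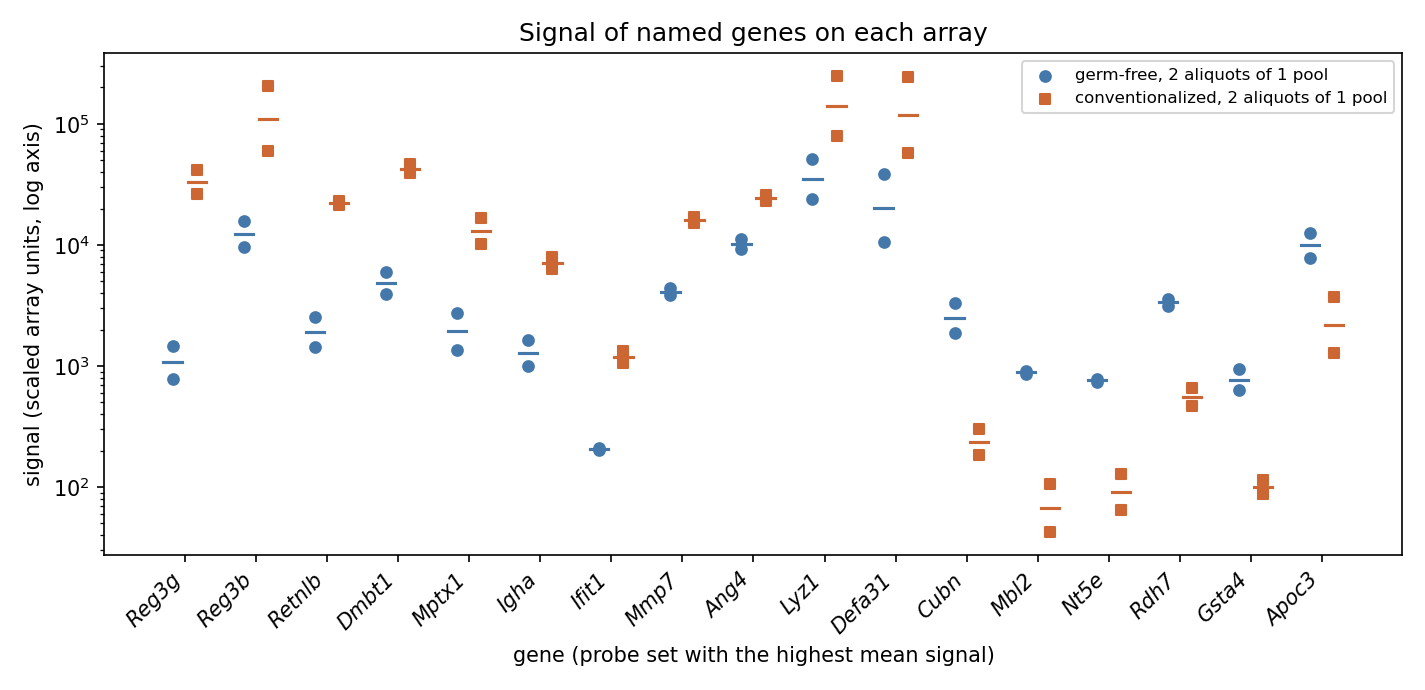
Signal of 17 genes on each array, on a log axis in the scaled units of the arrays; circles are the germ-free and squares the conventionalized arrays, 2 aliquots of 1 pool each, and lines are geometric means. Reg3g lies at 786 and 1460 against 26467 and 41251, and Cubn at 1872 and 3315 against 185 and 301; Reg3b, Mmp7, Ang4, Lyz1 and Defa31 were not called at the probe sets drawn.

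Other host defence genes gave a mixed account. Of 12 measured members of the list of other epithelial antimicrobial proteins, Retnlb rose and 11 did not pass, and the list median was 0.84 (0.31 with quantile normalization, 0.51 without conventionalized replicate 2). Retnlb is also a goblet cell product, and the 19 goblet cell markers had a median of 0.15 (-0.02 with quantile normalization, -0.16 without germ-free replicate 1) with Retnlb alone called. Among the 7 Reg family lectins Reg3g was called. Adjusted over the list alone, Reg3g and Reg3b were higher and Reg3a (-1.12) and Reg4 (-1.19) lower, the last pair named after their values were seen. Pla2g5, a secreted phospholipase, rose from signals of 55 and 12 to 526 and 879. With 12 under the pseudocount of 32, the size of this rise is set by the pseudocount, at 2.34 with 128 and 4.27 with 8 on the log2 scale, and its call was lost in the brightest 25% of probe sets and without conventionalized replicate 2. Smaller rises among the 12 largest were those of Cklf, Cog4, Upk1b and Etf1, from 2.00 to 1.80, each of which lost its call with quantile normalization, with median centring and without conventionalized replicate 2. Other tested probe sets of these 4 genes reached down to -0.13 for Cklf, -0.64 for Cog4, -1.21 for Upk1b and -0.15 for Etf1. Of all tested, 2 of 3 were higher for Cklf, 1 of 3 for Cog4, 2 of 4 for Upk1b and 4 of 5 for Etf1. Both higher probe sets of Upk1b were called. Of 21 genes described as responding to colonization in whole intestine, Reg3g and Retnlb rose and 19 did not pass, with a median of 0.40 (-0.12 with quantile normalization, 0.20 without conventionalized replicate 2 and 0.66 without conventionalized replicate 1). The list does not record the direction described for each gene, so its median cannot show whether those responses recurred here. Fut2, a fucosyltransferase, differed by 0.09 ± 0.87, and Angptl4, an inhibitor of lipoprotein lipase, by 0.77 ± 0.45. A second Fut2 probe set lay under the signal filter and was not tested. It read 24 and 21 in germ-free and 69 and 247 in conventionalized cells.

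Interferon response genes had a median log2 difference of 0.74, above all 10000 random lists, with 18 of 21 members above 0. Ifit1, an interferon-induced RNA-binding protein, rose 5.13-fold, from 204 and 209 to 1056 and 1340. Ifit1 was the sole member called over all probe sets at its brightest probe set, though not without conventionalized replicate 2. Its relative Ifit1bl1, outside the list, rose 3.19-fold, a call lost with quantile normalization, with median centring and with any 1 array left out. Adjusted over the list alone, Igtp (1.46) and Oas1a (1.35) also passed, both named after their values were seen. Psmb8, a member of the list also named after its values were seen, differed by 0.79 at its brightest probe set. Its other probe set differed by 1.80 and was called. The 13 antigen presentation genes had a median of 0.77 with 8 above 0, and none was called over all probe sets at its brightest probe set, while H2-Aa (1.55) and H2-Ab1 (1.74), the latter named after its value was seen, passed when adjusted over the list alone. A second probe set of H2-Aa differed by 1.75 and was called. The list median was 0.43 without germ-free replicate 2, and 1 member was called with a pseudocount of 8 and in the brightest 25% of probe sets. B2m (-0.01) and Ctss (-0.25) differed by less than their standard errors.

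Genes of absorption and detoxification lay mostly lower. Whether they fell within Paneth cells or through less absorptive enterocyte RNA in the capture was not tested. The 26 xenobiotic and glutathione metabolism genes had a median of -0.70, below all 10000 random lists, with 20 below 0. Gsta4, a glutathione transferase for lipid peroxidation products, fell by 2.60 on the log2 scale, and 8 members were lower and 1 higher when adjusted over the list alone. The 28 absorptive enterocyte markers had a median of -0.55, also below all 10000 random lists, with 23 below 0. That median was -0.22 without germ-free replicate 2, -0.37 without conventionalized replicate 1 (16 below 0), and -0.98 without germ-free replicate 1 or conventionalized replicate 2. Apoc3, an apolipoprotein of triglyceride-rich particles, fell by 2.16, from 7779 and 12602 to 1270 and 3741, and 3 members passed when adjusted over the list alone. Rdh7, a retinol dehydrogenase, fell by 2.54, Nt5e, the ectoenzyme that makes adenosine from AMP, fell by 2.67, and Akr1c14, an aldo-keto reductase, fell by 2.41. Further falls among the 12 largest were those of Lhfpl2, Nat8f4, Clec2e, Vwce, Acy1 and Dusp6, from -3.13 to -2.37. All but Lhfpl2 of these 6 lost their calls with quantile normalization and with either germ-free array left out, Lhfpl2 lost its call without germ-free replicate 2, and Dusp6 was called in 5 of 16 alternatives. With quantile normalization Gsta4, Apoc3, Nt5e and Akr1c14 lost their calls and Rdh7 kept its own. Gsta4 and Nt5e lost theirs without either germ-free array, Akr1c14 and Apoc3 without germ-free replicate 2, and Apoc3 also without conventionalized replicate 1 and with median centring. Fabp1, a fatty acid binding protein of enterocytes, differed by -0.04 ± 0.52.

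Beside goblet cells and enterocytes, a crypt section can hold further cell types, and Igha was the sole gene of their lists to be called at its brightest probe set. Igha, the constant region of immunoglobulin A, rose 5.42-fold, from 994 and 1644 to 6273 and 7988, and all 3 of its probe sets were called, though with median centring the brightest was not. The 7 other B and plasma cell markers did not pass. Enteroendocrine markers had a median of -0.55 with 18 of 20 below 0 and none called, for example Gcg at -1.04 ± 0.42 and Gip at -0.95 ± 0.43. With a pseudocount of 8, in the brightest 25% of probe sets and without conventionalized replicate 1, 1 member was called lower; without conventionalized replicate 2 the median was -0.35. The 17 crypt base stem cell markers had a median of -0.24, with Olfm4 at 0.27. Prom1, at 1.42 ± 0.45, was higher when adjusted over that list alone. Further medians were 0.11 for 8 tuft cell, 0.20 for 13 T and innate lymphoid, 0.08 for 13 macrophage, dendritic and granulocyte, -0.08 for 25 fibroblast, -0.30 for 12 smooth muscle, -0.19 for 11 endothelial and blood, 0.36 for 6 enteric neuron and glia, and -0.01 for 13 exocrine pancreas markers. No member of these lists, the stem cell list included, was called over all probe sets. With 1 array left out, these medians changed sign for all but the T and innate lymphoid and the enteric neuron lists, which went to 0.03 and 0.08 without germ-free replicate 2. Examples of a changed sign were shifts to 0.22 for stem cells without conventionalized replicate 2, and to 0.19 for smooth muscle and 0.42 for endothelial and blood markers without conventionalized replicate 1. In the macrophage list 1 member was called without germ-free replicate 1 and 1 without conventionalized replicate 2.

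Of the regulatory and metabolic lists, the circadian clock genes held 1 called member, Dbp, a clock-controlled transcription factor that fell by 1.87 (not called with quantile normalization, with median centring, or without germ-free replicate 2 or conventionalized replicate 1), and 10 members that did not pass (median -0.11). No member was called among 16 immediate early and stress genes (median -0.43, Fos at -0.70 ± 0.43), 20 sterol and fatty acid synthesis genes (-0.31, Hmgcs1 at -0.94 ± 0.60), 17 fatty acid oxidation genes (-0.27), 32 cell cycle genes (0.31), 32 secretory pathway genes (-0.03, or 0.01 with quantile normalization, Xbp1 at 0.54 ± 0.58), 16 autophagy genes (-0.17), 20 Toll-like receptor and NF-kB genes (0.13, Nfkbia at 0.36 ± 0.61) or 22 Wnt, Notch and Paneth differentiation genes (-0.01). For the sterol list, 1 member was called lower with quantile normalization. With 1 array left out, the medians of the circadian, fatty acid oxidation, secretory pathway, autophagy, Toll-like receptor and Wnt lists changed sign, and those of the immediate early and sterol lists did not. The cell cycle median ran from 0.10 without germ-free replicate 1 to 0.50 without germ-free replicate 2.

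**Figure D3:**
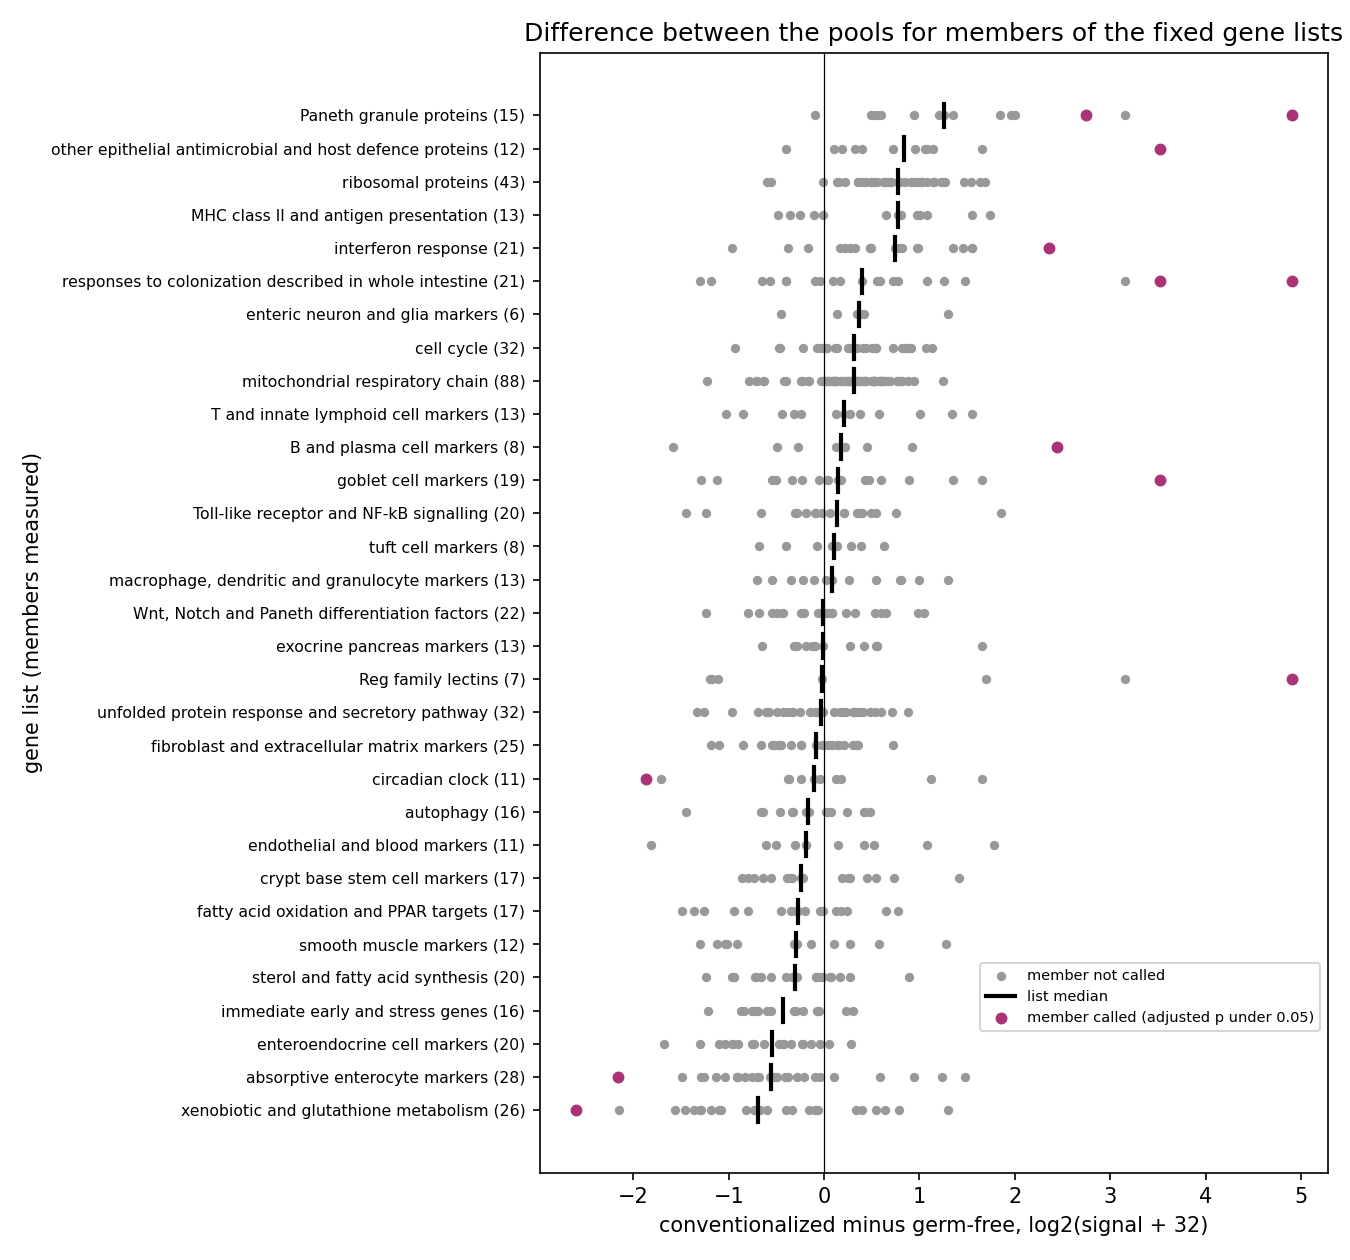
Log2 differences, conventionalized minus germ-free, of the measured members of 31 gene lists, sorted by list median; each point is 1 gene, coloured points are genes called by limma, and vertical bars are list medians. Medians drawn run from -0.70 (xenobiotic and glutathione metabolism) to 1.25 (Paneth granule proteins), the latter being 0.82 with quantile normalization. The alpha-defensin list, with 2 members measured and a median of 2.19, is not drawn.

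Probe sets that differed by at least 2-fold in all 4 pairs of arrays gave a wider count that needs no variance model. There were 176 higher and 213 lower in the conventionalized pool, 389 together, among them Reg3g and Cubn. The other 2 ways of splitting the 4 arrays, each of which mixes the pools, gave 328 and 616, so the count of the true split was not the highest. The groups did not overlap for 31.1% of probe sets, where chance gives 33.3%. By limma the other splits gave 30 and 0 called probe sets, against 75, but the split with 0 called had 1680 probe sets at an unadjusted p under 0.05 against 1154, and a standard deviation of the differences of 0.71 against 0.66. The split by aliquot number had 13 probe sets over a log2 difference of 3, as many as the true split, and among the 11222 brightest probe sets its largest difference was 4.93, against 5.05 in the true split.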

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

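The tests of the hybridization controls and of the 3'/5' ratios, and the comparison of Paneth with goblet, enteroendocrine and stem cell lists, were chosen only after the results were seen.

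Of the array control probe sets, which no comparison above uses, 3 kinds were brighter on the conventionalized than on the germ-free arrays. The hybridization controls, bacterial transcripts added in fixed amount to each hybridization mix, were 4.74 times higher, the 18S ribosomal RNA probe sets 2.40 times and the B2 repeat probe set 2.38 times. The hybridization controls read 4835 and 10107 on the germ-free and 16589 and 66250 on the conventionalized arrays. The polyA controls went the other way, at 0.704 times the germ-free level, with 11627 and 25772 against 13931 and 10653. The 3'/5' signal ratio of Actb, a sign of RNA length, was 39.2 and 44.9 on the germ-free and 63.7 and 116 on the conventionalized arrays, and that of Gapdh 6.29 and 10.3 against 9.39 and 6.43. Fluidics station and group cannot be told apart for these values.

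Conventionalized replicate 2 stood apart from the 3 other arrays. Its hybridization controls were 3.99 times those of the next array after scaling, a value consistent with less labelled cRNA bound on that array, which scaling to a common mean would then have made up for. Shorter amplified RNA cannot be told apart from the other explanations: the 3'/5' signal ratio of Actb was highest on that array, at 116, and higher on both conventionalized than on both germ-free arrays, while that of Gapdh, 6.43, was not the highest. No biological explanation was tested, since the array shares its pool with replicate 1.

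Paneth granule proteins and alpha-defensins lay mostly higher in the conventionalized pool, with a median log2 difference of 1.36 over 17 genes. Of these, 2 of 15 granule proteins and 0 of 2 alpha-defensins were called over all probe sets. Scaling that acts on the brightest probe sets was argued against as the whole explanation, since quantile normalization left a median of 1.08, more than the duplicate spread of 0.24 above the bound of 0.5 set beforehand, although Lyz1 went from 2.00 to -0.12. Less absorptive enterocyte RNA in the capture may contribute: of the 10 brightest enterocyte markers, 8 were lower, just at the bound set beforehand, and 10 with quantile normalization. The 2 brightest, Fabp2 and Apoa4, named after their values were seen, were higher, by 1.475 and 0.587. Fabp1, counted among the 8, differed by only -0.04. Of all 28 markers, 16 were lower without conventionalized replicate 1, against 23. Less enterocyte RNA was argued against as the whole of the difference, since removing it would raise other crypt cells alike. The highest median of the goblet, enteroendocrine and stem cell lists was 0.15. That comparison covers an even loss of enterocyte RNA only, and the share of Paneth cells in the capture was not tested. A response of Paneth cells to colonization remains a hypothesis among these.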

How the results depend on the processing

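Array weights, the robust prior, the fixed prior, the crossed block and the pairwise counts with an array left out were chosen after the data were seen. Of 26 named genes called, none kept its call in all 16 alternatives, since no probe set at all was called without the trend or with the fixed prior. Reg3g, Retnlb, Cubn and Rdh7 lost their calls only there. None of the 26 changed sign in any alternative. Their groups do not overlap, however, so only quantile normalization and median centring could have changed a sign. Of 92 named genes not called, 83 were called in no alternative and 42 changed sign in at least one. Of 351 list medians recomputed, 303 moved by less than the duplicate spread and 48 by more. Leaving out 1 array can hardly move a median by more than that spread, which is built from the same duplicate differences. For those alternatives the count is therefore no test of stability. The respiratory chain median, for example, went from 0.31 to -0.02 without germ-free replicate 1, within its spread of 0.40. The planned block on scan or hybridization batch was not run: chip lot, scanner, hybridization day and scan day each took 1 value over all 4 arrays, which leaves no block to fit, and each fluidics station held 1 group. Dim signal limits the rest: 21.4% to 28.6% of values per array lay under the pseudocount of 32.

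Called probe sets numbered 14 higher and 19 lower with quantile normalization (23 shared with the 75), 6 and 21 with median centring, and 0 and 0 both without the trend and with the fixed prior of 4 degrees of freedom. Without the trend the prior had 7.22 degrees of freedom. Leaving out 1 array, the lone array assumed to vary like the other group, gave 14 to 34 higher and 7 to 181 lower. The Paneth granule median was 0.82 with quantile normalization and 1.12 to 1.62 with 1 array left out.

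Aliquot numbers are shared by the groups, but only 2 pairs exist. The replicate block gave 13 called higher and 17 lower, the correlation of aliquot deviations being -0.13. Crossing the aliquot pairing gave 71 higher and 157 lower.

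Probe sets at least 2-fold apart in all 4 pairs numbered 53 higher and 82 lower with a pseudocount of 128, 569 and 559 with no filter, and 52 and 88 in the brightest 25%. With 1 array left out they numbered 362 to 1473 higher and 522 to 2200 lower, fewer pairs being required. For the agreement of duplicate amplifications, the Pearson r of conventionalized duplicates was 0.728 with a pseudocount of 8, 0.854 with 128 and 0.863 in the brightest 25%. The share over 2-fold apart was 8.82% (germ-free) and 15.5% (conventionalized) with 128, and 12.9% and 17.1% in the brightest 25%. The cause of these changes was not tested, beyond what fewer probe sets, a larger pseudocount or fewer arrays do by construction.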

Other observations

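The 2 tests of explanations in this part were planned before the results were seen, except for the choices a sentence names. Immunoglobulin probe sets were looked at together after the rise of Igha was seen. Of 20 tested, including those that name several genes, 17 had a log2 difference above 0 and 4 were called, with a median of 1.46. The 4 were the 3 probe sets of Igha and 1 of the kappa light chains. Ighm, the heavy chain of immunoglobulin M, differed by 0.45 at its brightest probe set. Its other probe sets ran from 0.02 to 2.58, and none was called.

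Immunoglobulin transcripts are made by plasma and B cells, which lie close to crypt bases. More lamina propria tissue of every kind in the conventionalized capture was argued against, since 2 of its 3 lists lay under the bound of 0.25 set beforehand by more than their duplicate spread. The 25 fibroblast and matrix markers had a median of -0.082, with a spread of 0.02, and the endothelial list one of -0.19, with a spread of 0.32; the macrophage list, at 0.08 with a spread of 0.34, did not lie clearly under it. Without conventionalized replicate 1 the endothelial median was 0.42, while the fibroblast median was 0.05 at most with any array left out. More plasma or B cells cannot be told apart from other explanations. The 6 markers that are not immunoglobulin genes had a median of -0.074, with a duplicate spread of 0.29, which would have counted against more such cells under the bound of 0.25 set beforehand. That bound was judged wrong after the result was seen, because the list joins 2 kinds of marker that lay on opposite sides of 0, and plasma cells do not need the B cell genes. The division into kinds was made, and the 6 genes were named, after their values were seen. The plasma cell genes Jchain, Prdm1 and Mzb1 differed by 0.93, 0.22 and 0.13, less than the immunoglobulin median, and the B cell genes Blk, Cd22 and Ms4a1 by -0.27, -0.49 and -1.58. None of the 6 was called, and 3 genes of a kind are too few to decide. Blk, Cd22, Ms4a1 and Mzb1 were also dim, with mean signals from 157 to 231 against a filter of 113.9, which limits what their differences can show.

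Among 61 genes with a called probe set, 31 had more than 1 probe set tested and in 10 of these the probe sets lay in both directions. Malat1 was chosen after its values were seen. The largest fall of any probe set was 1 of 7 for Malat1, a nuclear noncoding RNA, with signals of 3081 and 1398 in germ-free and 103 and 67 in conventionalized cells (log2 difference -4.19), while the other 6 differed by -0.72 to 0.84 and none of those was called.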
